A study of Mus musculus with 11 samples.

How the data were processed

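RNA was measured on single-colour mouse oligonucleotide arrays in T cells of the B10.BR strain after 4 days of culture with dendritic cells of the C57BL/6 strain. These strains differ in their major histocompatibility genes, so the T cell response is an alloresponse. Per the labels, the dendritic cells came from liver, from the organs abbreviated MLN and PLN, or from spleen. MLN and PLN are the customary abbreviations of mesenteric and peripheral lymph node, but the labels do not spell them out and the abbreviations are kept here. Liver, MLN and PLN had 3 arrays each, numbered 2, 3 and 4, and spleen had 2, numbered 3 and 4. Each array was assigned to its organ and number from its own label.

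The deposited table holds 1 intensity per probe set and array on a linear scale, which the authors had scaled and had not log-transformed. That scaling was read from the values: after trimming 2% at each end, the mean intensity was 500.2 on every array. The software and the summarisation of probes behind these values are not given in the sources used here. The table has 22690 probe sets, with intensities from 0.1 to 21556.3. Of these, 64 control probe sets were left out. The annotation listed 1 gene symbol for 20393 probe sets, several for 691 and none for 1606, and symbols were brought to those of the mouse reference GRCm38.p6 for 20364. Probe sets with several symbols or none were not named or tested.

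Intensities were transformed as log2(intensity + 16). The median log2 values of the arrays spanned 0.22, above the tolerance of 0.05 set for leaving them unscaled, and the arrays were quantile normalized. For each of 12393 genes the probe set with the highest mean was used; 4956 genes had several probe sets. The 7436 genes in the upper 60% by mean level, which lies above an intensity of 104.7, were tested. Log2 differences are on the log2(intensity + 16) scale and understate the change of genes of low intensity.

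Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a variance trend and Benjamini-Hochberg adjustment at 0.05. All 11 arrays entered 1 fit with 4 organ means and 7 residual degrees of freedom. A moderated F-test compared the 4 organs, each organ was set against the mean of the other 3 organ means, and each pair of organs was compared. The labels give neither a reference organ nor T cells without dendritic cells. The lists comprised 20 gene lists and 15 lists of cell type markers, with 463 entries, of which 413 matched a measured gene. Of these 35 lists, 29 had at least 3 tested genes. They were tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29 lists of each organ. No list call held when the correlation was estimated from the data, in either fit. Counts of list members are given over all genes tested and adjusted over the list alone.

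The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each organ, up to 10 genes in each direction with the largest difference among those passing, filled with the genes of smallest p to 5 where fewer passed. It also takes up to 4 members of smallest p for each list, the 10 genes of smallest p in the F-test, up to 3 in each direction per pair, and a fixed set of homing, cytokine and lineage genes. Other genes are said to have been chosen after their values were seen.

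The replicate numbers pair the arrays. After the organ means were subtracted, the 15 pairs of arrays with the same number correlated at 0.412 to 0.731 across genes, and the 30 pairs with different numbers at -0.708 to 0.0843. All 11 arrays correlated best with an array of their own number. The number accounted for 57.9% of the variance of the tested genes, the organ for a further 22.0%, and 20.1% was left. The fit fixed in advance has no block. The fit with the number as a block, called the blocked fit, was set before the data were seen and has 5 residual degrees of freedom; its value stands beside each result whose call or count it changes. The labels do not say that arrays of 1 organ come from separate cultures or animals, so p-values measure the spread between these arrays, which may be technical.

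Arrays correlated pairwise at 0.965 to 0.984 and no 2 arrays held identical values. Median intensities ran from 144.3 to 170.4, the share of probe sets below an intensity of 16 from 12.9% to 16.5%, and the ratio of 3' to 5' actin probe sets from 1.08 to 1.15. The number of arrays limits the precision. On simulated data with 200 of 7436 genes changed in MLN, the unblocked fit recovered 22% of changes of 0.5 (log2), 84% of 1, 96% of 1.5 and 98% of 2, with 0 false calls among 150. The blocked fit recovered 70%, 94%, 98% and 100%, with 8 false calls among 189. In the same simulations both fits called 0 genes between PLN and spleen, where nothing had been changed. The simulated noise was normal and independent between genes, so these rates may be better than those on real arrays.

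Alternatives were the replicate number as a fixed or a random block, intensities as deposited, median centring, pseudocounts of 1 and 64, no level filter, the upper 40% of genes, the mean of a gene's probe sets, each probe set alone, no variance trend, only the 2 organs of a pair, an estimated correlation, ranks, and each array left out in turn. The same settings within the blocked fit, and leaving out all arrays of 1 number, were added after the data had been seen. A spleen array numbered 2 was not analysed here.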

Results

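The series asks whether dendritic cells from different organs drive different responses in alloreactive T cells. Gene expression was measured in T cells after 4 days with dendritic cells from liver (n = 3), MLN (n = 3), PLN (n = 3) or spleen (n = 2). T cell transcripts were abundant on all arrays: Cd8a had mean log2 intensities of 11.66, 11.78, 11.48 and 11.60 in liver, MLN, PLN and spleen cultures, and Cd4 had 10.11, 9.79, 9.88 and 10.28. Class II genes of antigen-presenting cells were also measured, with Cd74 at 10.74, 10.52, 10.73 and 10.74 and H2-Aa at 9.38, 9.38, 9.44 and 9.38. The first principal component held 43.9% of the variance and separated the arrays numbered 3 from those numbered 4; the next 2 held 15.4% and 13.0%.

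**Figure D1:**
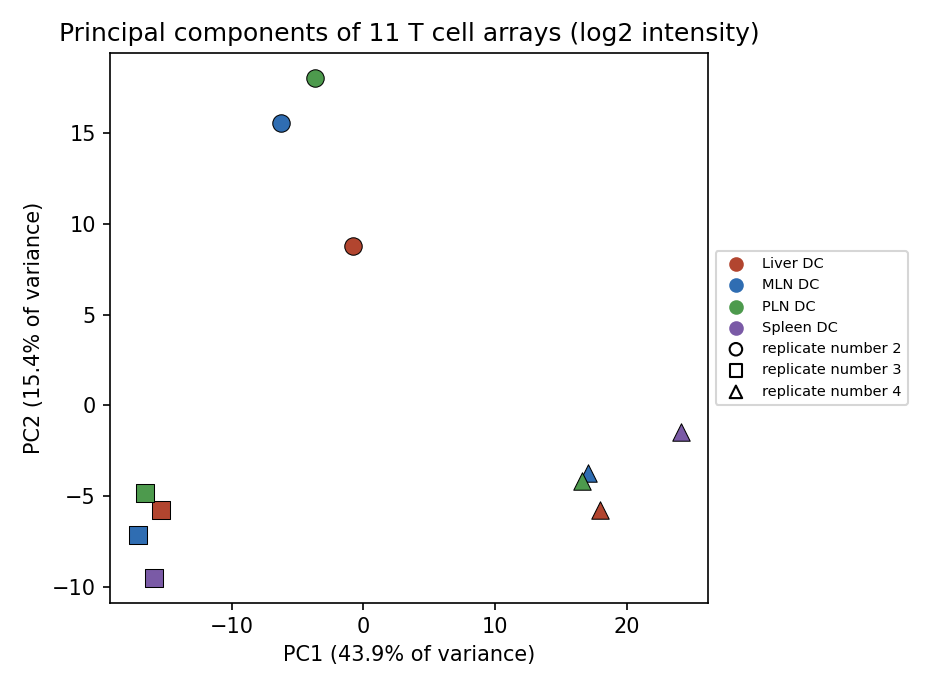
Principal components of the 7436 tested genes, with each array as a point, colour for the organ of the dendritic cells and symbol shape for the replicate number. Arrays sharing a number lie together, with 43.9% of the variance on the first component and 15.4% on the second.

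The 4 cultures differed in Lmna, Fut7 and Hic1. Lmna, which encodes A-type lamins of the nuclear envelope, had mean log2 intensities of 9.54 ± 0.42 in liver, 7.09 ± 0.27 in MLN and 9.07 ± 0.19 in PLN (SD, n = 3), and 8.93 ± 0.21 in spleen (SD, n = 2). Fut7, a fucosyltransferase that completes selectin ligands on T cells, was likewise highest in liver, at 8.29 ± 0.10, and lowest in MLN, at 6.46 ± 0.34, with 7.52 ± 0.09 in PLN and 7.72 ± 0.06 in spleen. Hic1, a transcriptional repressor, ran the other way, from 8.40 ± 0.24 in liver to 9.88 ± 0.12 in MLN, with 9.07 ± 0.07 in PLN and 9.11 ± 0.28 in spleen. In limma's F-test these 3 genes passed, with adjusted p = 0.0133, 0.0231 and 0.0341. The next 7 genes did not pass: Mpp2, Plxnc1, P2rx4 and Sema4a (adjusted p = 0.102 each), Il1b (0.105), Gcnt2 (0.107) and Csgalnact1 (0.151). The blocked fit called 148 genes, including the first 3, and a random block by number 51. The count was 0 without Liver replicate 2, MLN replicate 2, MLN replicate 4 or PLN replicate 2, and 1 without Liver replicate 3, MLN replicate 3, PLN replicate 3 or PLN replicate 4. The blocked count was 35 without Liver replicate 2, 42 and 50 without MLN replicates 4 and 2, 65 without Liver replicate 4, 73 and 82 without PLN replicates 4 and 2, and 92 without MLN replicate 3.

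T cells cultured with MLN dendritic cells differed from the rest in 7 genes without the block; with the block more genes were called for liver, 159 against 99 for MLN. Lmna fell by 2.09 (SE 0.18) on the log2 scale against the mean of the other organs, and Fut7 fell by 1.38 (SE 0.15). Sema4a, a semaphorin of immune cells, fell by 1.45 (SE 0.19), Plxnc1, a semaphorin receptor, by 1.11 (SE 0.14), and Mpp2, a membrane-associated guanylate kinase family member, by 1.46 (SE 0.18). Hic1 rose by 1.02 (SE 0.13) and P2rx4, an ATP-gated channel, by 0.75 (SE 0.11). Among genes that did not pass, the purinergic receptor P2rx7 differed by 1.01, the kinase Pim1 by 0.38 and Enpp4, an ecto-enzyme that splits nucleotides, by 0.86. In limma 7 of 7436 genes passed, 2 higher and 5 lower; adjusted p was 0.00192 for Lmna, 0.00661 for Fut7, 0.0125 for Hic1, Mpp2 and Plxnc1, 0.0180 for Sema4a and 0.0366 for P2rx4. With intensities as deposited the split was 1 higher and 6 lower. The blocked fit called 99 genes (59 with a random block by number), 53 higher and 46 lower, with these 7 among them as well as P2rx7 (adjusted p = 0.0280), Pim1 (0.00449) and Enpp4 (0.00320); after median centring it called 63 higher and 33 lower. With the block another Lmna probe set of lower intensity differed by -0.62 in MLN and further ones by 0.53 and -0.02, while the other probe sets of Plxnc1, Sema4a and P2rx4 moved the same way as those reported.

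Lmna and Fut7 stayed past the threshold whichever array was left out. The count was 2 without MLN replicate 3. Hic1 no longer passed without MLN replicate 2 (adjusted p = 0.130) or MLN replicate 3. Mpp2 and Plxnc1 did not pass without MLN replicate 3 (0.107 and 0.0863), nor Sema4a without MLN replicate 2 (0.166), MLN replicate 3 or PLN replicate 3. P2rx4 passed only with all arrays or without PLN replicate 2 or Spleen replicate 4, and had 0.348 without MLN replicate 2; with intensities as deposited it had 0.0575. All 7 stayed past the threshold of the blocked fit whichever array was left out, where P2rx7 did not pass without PLN replicate 3 (0.0539), Spleen replicate 3 or Spleen replicate 4, nor Pim1 without MLN replicate 2 (0.0532). The blocked count was 34 without MLN replicate 4, 40 without MLN replicate 2, 57 without PLN replicate 3 and 60 without MLN replicate 3.

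**Figure D2:**
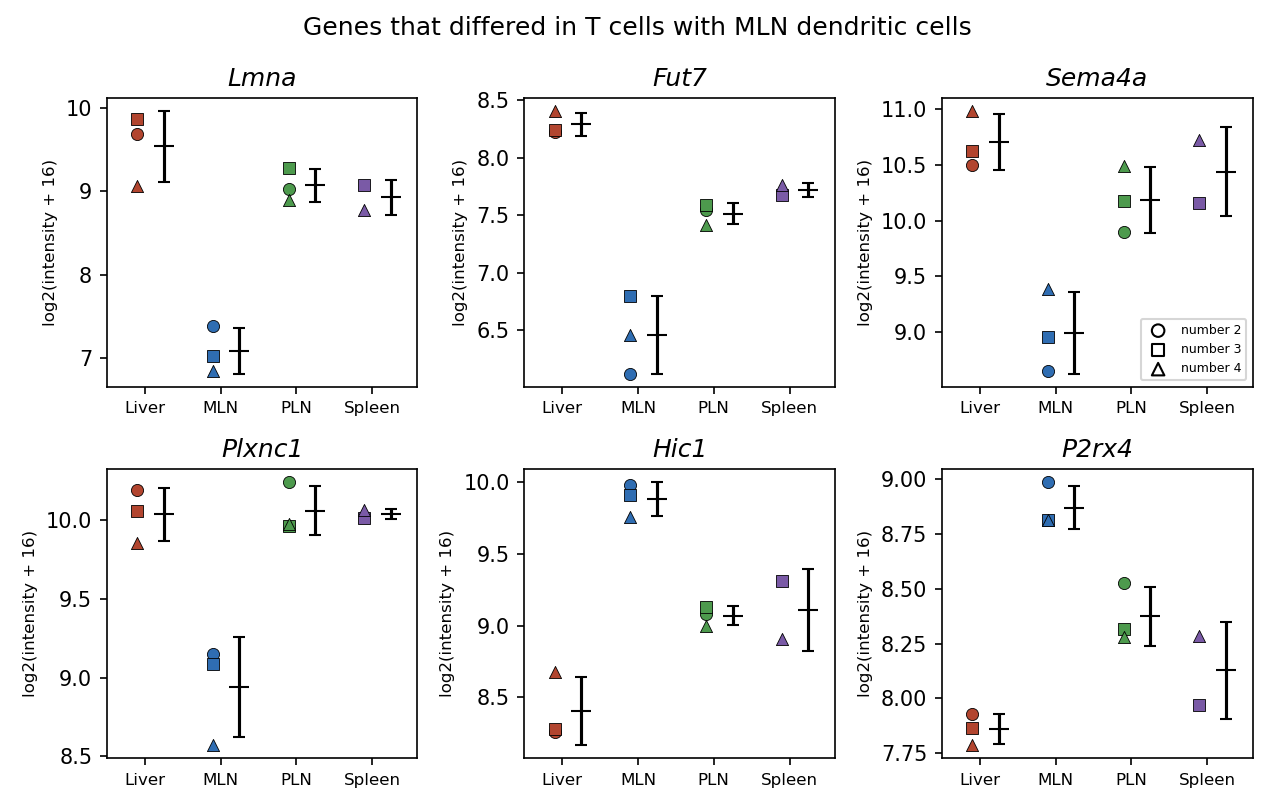
Quantile-normalized log2(intensity + 16) of selected genes on each array, with points for arrays, symbol shape for the replicate number, and the organ mean and SD beside the points. Lmna and Fut7 are lowest in MLN cultures, at means of 7.09 and 6.46, and Hic1 is highest there, at 9.88.

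Several fixed gene lists were shifted in MLN cultures. The mean that MLN is set against holds liver, so part of a shift opposite to that in liver comes from the liver arrays. This applies to the type 2 and glycolysis lists, with medians of -0.61 and -0.17 in liver. It applies also to the skin and selectin-ligand homing and T cell lists, with medians of 0.16 and 0.11 there, neither called. That mean holds spleen too, where the macrophage list had a median of 0.29, so its lower value in MLN is not separate from that shift. The skin and selectin-ligand homing list was lower, with 7 of 9 genes below the other organs and a median of -0.22 (camera adjusted p = 0.0181; adjusted p = 0.355 with an estimated correlation). Fut7 fell, and without the block it was also the only member passing when adjusted over the list alone; in the blocked fit 5 fell and 1, Ccr4, rose over the list alone. The chemokine receptor gene Ccr4, at 0.50, Gcnt1, at -0.65, and Cd44, at -0.33, did not pass over all genes tested. The type 2 T cell list was higher, with 9 of 11 genes above the other organs and a median of 0.50 (0.00146; adjusted p = 0.610 with an estimated correlation). Its members with the smallest p were Il4ra at 0.54, Ecm1 at 0.97, Nfil3 at 0.63 and Ccr4. In limma 0 of the 11 passed over all genes tested (4 at an unadjusted p under 0.05), 1 rose when adjusted over the list alone, and 3 rose in the blocked fit, including Il4ra (adjusted p = 0.0130) and Ecm1 (0.0190), with 6 over the list alone. The glycolysis and hypoxia list was higher too, with 14 of 17 genes up and a median of 0.11 (0.0193; adjusted p = 0.632 with an estimated correlation). That median depended on the scaling, at 0.20 with intensities as deposited and 0.27 after median centring (2.96e-06 and 3.94e-05). Between these settings all genes moved together, with a median over all genes of -0.02 and 0.05. Here limma passed 0 genes (1 at an unadjusted p under 0.05; 0 adjusted over the list alone), and the blocked fit passed 2, Hk2 at 0.38 (0.0156) and Egln3 at 0.36 (0.0318), with 4 over the list alone. Pfkp, at 0.19, and Pkm, at 0.11, did not pass.

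Markers of T cells and of macrophages were lower in the same MLN cultures. All 8 T cell markers lay below the other organs, with a median of -0.10 (0.0296; adjusted p = 0.610 with an estimated correlation), and the largest differences were those of Cd2, at -0.52, and Cd5, at -0.44; Cd247, at -0.11, and Cd3g, at -0.10, followed. Among 6 macrophage, monocyte and Kupffer cell markers 4 were lower, with a median of -0.27 (0.0382; adjusted p = 0.393 with an estimated correlation), with Cd14 at -1.12, Lyz2 at -0.60, Csf1r at -0.28 and Ctss at -0.27. In each of these lists limma passed 0 genes over all genes tested (2 at an unadjusted p under 0.05), and 1 fell when adjusted over the list alone. The blocked fit passed 1 gene in each, Cd2 (adjusted p = 0.00452) and Cd14 (0.0323), with 2 and 3 over the list alone, but neither list (0.0703 each). The T cell list was also not called with intensities as deposited (median -0.07; 0.237) or after median centring (median -0.0031; 0.271). Median centring moved all genes together, with a median over all genes of 0.05 in MLN, against -0.02 as deposited. The list lay below that median in both settings. Dendritic cell markers had a median of 0.21 (0.204; 12 genes), with H2-Ab1 at 0.33, Cd74 at -0.21, Ccl17 at 0.36 and Batf3 at 0.22. The gut homing list, with 4 tested genes, had a median of 0.16 (0.290). Its integrin gene Itga4 stood at 1.12 (limma adjusted p = 0.327; blocked 0.0502), Itgb7 at 0.18, Itgae at -0.45 and Itgb1 at 0.14; adjusted over the list alone, 1 rose and 1 fell.

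Camera called 5 of 29 lists in MLN cultures, and 3 in the blocked fit. The count of 5 was 2 without PLN replicate 3 and 3 without Liver replicate 3, MLN replicate 2 or MLN replicate 3. The homing list was not called without MLN replicate 2 (0.0836), the type 2 list without MLN replicate 3 (0.313), and the glycolysis list without Liver replicate 3, MLN replicate 2, MLN replicate 4 (0.353), PLN replicate 3 or Spleen replicate 3. The T cell list was lost without Liver replicate 4, MLN replicate 2 (0.413), MLN replicate 3, PLN replicate 3 or Spleen replicate 4. The macrophage list stayed called only without Liver replicate 4, MLN replicate 2, PLN replicate 2 or Spleen replicate 4, and had 0.205 without MLN replicate 3. The homing, type 2 and glycolysis lists kept their blocked calls whichever array was left out, and the blocked count of 3 was 10 without Liver replicate 3, 7 without MLN replicate 2, 6 without Spleen replicate 3 and 5 without Liver replicate 2 or MLN replicate 4.

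In T cells cultured with liver dendritic cells no gene passed the unblocked test. Each organ is set against the mean of the others, so part of the liver value of a gene that is low or high in MLN, such as Lmna, comes from the MLN arrays. Fut7 differed from the mean of the other organs by 1.06 (SE 0.15), Lmna by 1.18 (SE 0.18), and Pdcd1, an inhibitory receptor of activated T cells, by 0.88 (SE 0.16). Saa3, a serum amyloid gene, differed by 0.79 and Eml5 by 0.67, although with the block the other probe sets of Eml5 stood at -0.13 and -0.11, and those of Lmna at 0.37, -0.24 and -0.56. On the lower side were Hic1 at -0.95 (SE 0.13), Gcnt2, a glycan-branching enzyme, at -1.38 (SE 0.21), Csgalnact1, an enzyme of chondroitin sulfate synthesis, at -1.17 (SE 0.18), the elongation factor gene Eef1a2 at -0.90 and P2rx4 at -0.60. In limma 0 of 7436 genes passed (316 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0802, for Fut7 and Hic1. The blocked fit called 159 genes, 56 higher and 103 lower, and a random block by number 47. All of the named genes passed there, among them Lmna (adjusted p = 0.00108), Hic1 (0.00373), Fut7 and Gcnt2 (0.00392 each), Csgalnact1 and P2rx4 (0.00837 each), Pdcd1 (0.0127), Eef1a2 (0.0183), Saa3 (0.0293) and Eml5 (0.0321).

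The liver contrast leaned on single arrays. The unblocked count was 2 without Liver replicate 4 and 1 without MLN replicate 3. The blocked count of 159 was 7 without Liver replicate 2, 37 without Liver replicate 4, 56 without Spleen replicate 3, 60 without MLN replicate 2, 61 without PLN replicate 2 and 94 without PLN replicate 4. Without Liver replicate 2, Lmna alone of the 10 named genes passed the blocked fit. Without Liver replicate 4, Pdcd1, Saa3, Eml5, Csgalnact1 (adjusted p = 0.0811), Eef1a2 (0.139) and P2rx4 (0.0746) did not pass. Eef1a2 was also lost without MLN replicate 2, Saa3 without MLN replicate 2, PLN replicate 2 or Spleen replicate 3, and Eml5 in 8 of 11 cases, all but those without MLN replicate 3, PLN replicate 3 and Spleen replicate 4.

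Cell cycle genes were higher as a group in liver cultures, and type 2 T cell and glycolysis genes were lower. All 30 tested cell cycle genes lay above the other organs, with a median of 0.17 (camera adjusted p = 3.71e-08; adjusted p = 0.383 with an estimated correlation). Among them were Ccnb2 at 0.31, Kif20a at 0.40, Cdc20 at 0.24 and Cenpa at 0.22. In limma 0 passed over all genes tested (8 at an unadjusted p under 0.05) and 0 adjusted over the list alone; in the blocked fit Kif20a and Cdc20 rose (adjusted p = 0.0391 each) and 14 rose over the list alone. Of 11 type 2 T cell genes, 10 were lower, with a median of -0.61 (2.30e-06; adjusted p = 0.383 with an estimated correlation). They included the interleukin receptor gene Il4ra at -0.61, Ecm1 at -1.20, Nfil3 at -0.84 and Ccr4 at -0.58. Here 0 passed over all genes tested (4 at an unadjusted p under 0.05), 4 fell adjusted over the list alone, and 3 fell in the blocked fit: Il4ra (0.00869), Nfil3 (0.0116) and Ecm1 (0.0129), with 1 up and 8 down over the list alone. Of 17 glycolysis and hypoxia genes, 16 were lower, with a median of -0.17 (0.000144; adjusted p = 0.383 with an estimated correlation). Hk2, which encodes a hexokinase, stood at -0.50, Pfkp at -0.26, Egln3 at -0.67 and the glucose transporter gene Slc2a1 at -0.44. In this list 0 passed over all genes tested (3 at an unadjusted p under 0.05), 1 fell adjusted over the list alone, and 6 fell in the blocked fit, Egln3 (0.00108), Hk2 (0.00463), Pfkp (0.0161) and Slc2a1 (0.0341) among them, with 10 over the list alone.

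Type 1 T cell genes were higher in liver cultures, and regulatory T cell, unfolded protein response and apoptosis genes were lower. Of 17 type 1 genes 12 were higher, with a median of 0.25 (camera adjusted p = 0.0226; adjusted p = 0.461 with an estimated correlation). Cxcr3, a chemokine receptor of type 1 cells, stood at 0.80 and Il18r1 at 1.02, with Il18rap at 0.46 and Il12rb1 at -0.49. Limma passed 0 (4 at an unadjusted p under 0.05) and 1 adjusted over the list alone; the blocked fit passed 5 upward, with Cxcr3 (0.0148) and Il18r1 (0.0197), and 8 up and 1 down over the list alone. Of 15 regulatory T cell genes 12 were lower, with a median of -0.24 (0.00947; adjusted p = 0.335 with an estimated correlation). Nt5e and Entpd1, ecto-enzymes that make adenosine, stood at -1.04 and -0.38, the costimulatory receptor gene Tnfrsf18 at -0.47 and Nrp1 at 0.61. Limma passed 0 (2 at an unadjusted p under 0.05; 0 adjusted over the list alone) and the blocked fit 4, all lower, with Tnfrsf18 (0.00549), Nt5e (0.0466) and Entpd1 (0.0486), and 2 up and 8 down over the list alone. The unfolded protein and amino acid response list, with Xbp1 at -0.41 and Dnajb9 at -0.31, had 14 of 15 genes lower and a median of -0.12 (0.00264; adjusted p = 0.335 with an estimated correlation). Its genes Trib3 and Ddit3 were highest in PLN replicate 2 and MLN replicate 2, and the list stayed called when either array alone was left out. The other then remained, so this does not show whether the call depends on them together. Limma passed 0 of them in either fit (0 at an unadjusted p under 0.05, and 5 in the blocked fit); adjusted over the list alone it passed 0, and 5 fell in the blocked fit. The apoptosis list, with Bcl2 at -0.59 and Cdkn1a at -0.40, had 9 of 12 lower and a median of -0.11 (0.0304; adjusted p = 0.383 with an estimated correlation) and was not called in the blocked fit (0.153), although Cdkn1a fell there (0.0239). Limma passed 0 of its genes without the block (3 at an unadjusted p under 0.05; 0 adjusted over the list alone), and in the blocked fit 1 rose and 4 fell over the list alone.

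The blocked fit alone called 2 further lists in liver cultures. The cytotoxic granule and killer receptor list had a blocked median of 0.17 over 19 genes (camera adjusted p = 0.0155 blocked and 0.413 unblocked; blocked adjusted p = 0.453 with an estimated correlation). The killer receptor genes Klrk1, at 0.77, and Klrc1, at 0.56, rose there (limma adjusted p = 0.00458 and 0.0391), as 2 of 4 members that rose. Over the list alone 8 rose and 1 fell in the blocked fit. The 5 CD8 T cell markers had a blocked median of 0.18 and were not called (0.383 unblocked and 0.113 blocked); Ctsw, in both lists, rose in the blocked fit, at 0.39 (limma adjusted p = 0.0217). The type 17 T cell list had a blocked median of -0.19 over 6 genes (0.0494 blocked and 0.330 unblocked; blocked adjusted p = 0.344 with an estimated correlation), and Il17a and Ahr fell there by 0.84 and 0.57 (0.00392 and 0.0486), also over the list alone. Without the block 0 genes of either list passed in limma (1 and 0 at an unadjusted p under 0.05). The cytotoxic list lost its call without Liver replicate 4 (0.171) or Spleen replicate 3. The type 17 list lost it without any of the 3 liver arrays, MLN replicate 2, MLN replicate 4, PLN replicate 4 or Spleen replicate 3, and had 0.119 without Liver replicate 2.

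Camera called 7 of 29 lists in liver cultures, and 8 in the blocked fit. The count of 7 was 11 without Liver replicate 3 and 3 without Liver replicate 4. The cell cycle, type 2 and glycolysis lists stayed called whichever array was left out. Without Liver replicate 4 the type 1 (0.489), regulatory T cell (0.181), unfolded protein (0.186) and apoptosis (0.0953) lists were not called. The type 1 list was also lost without MLN replicate 2, PLN replicate 2 or Spleen replicate 3, the regulatory list without Liver replicate 2, MLN replicate 3 or MLN replicate 4, and the apoptosis list without Liver replicate 2, MLN replicate 4, PLN replicate 4 or Spleen replicate 4. In the blocked fit the type 1, regulatory and unfolded protein lists stayed called whichever array was left out. The macrophage list was not called in liver (camera adjusted p = 0.143, blocked 0.174), with 3 of 6 genes higher and a median of 0.06. Its list mean was higher in 3 of 3 numbers. In the blocked fit its member Lyz2 rose by 0.74 (limma adjusted p = 0.0424). Against MLN, its member Cd14 and the cytokine gene Il1b were 1.37 and 1.27 higher in liver there (0.0169 and 0.00243).

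**Figure D3:**
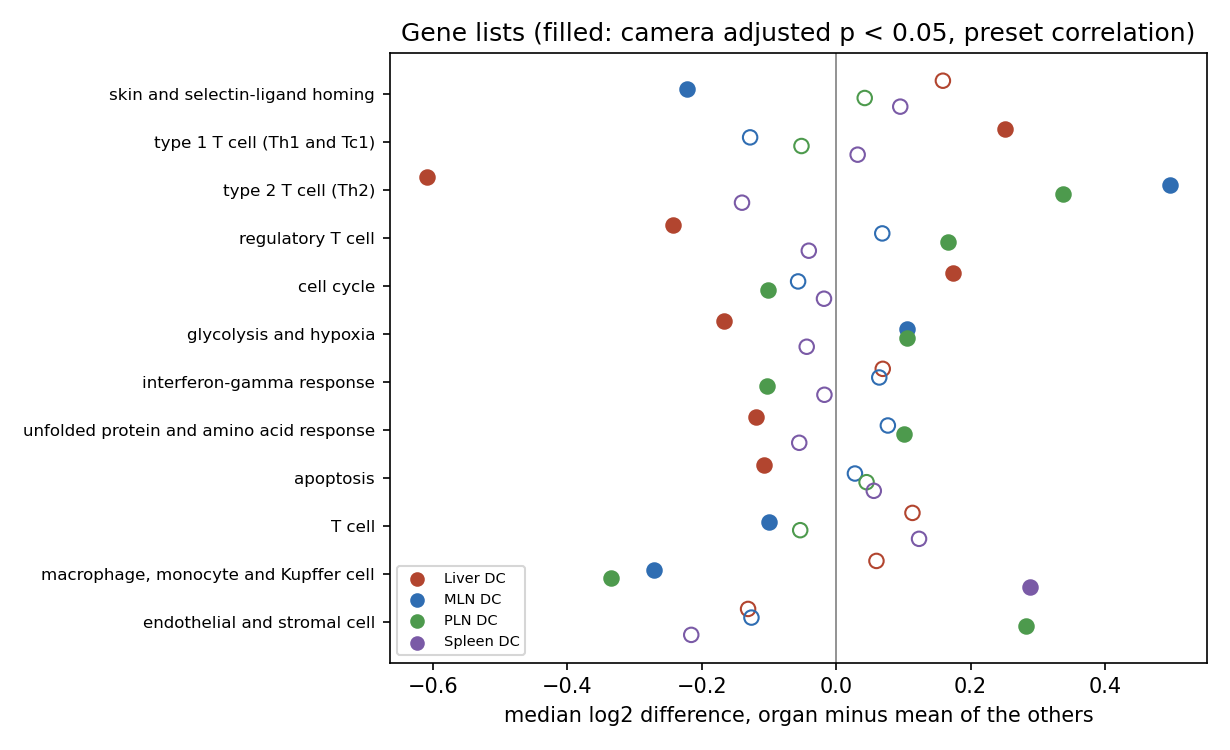
Median log2 difference of the tested genes of each called list, each organ minus the mean of the other organs, with colour for the organ and filled points where camera called the list without the block at its preset correlation. The cell cycle list lies at 0.17 in liver and -0.10 in PLN, and the type 2 T cell list at -0.61 in liver, 0.50 in MLN and 0.34 in PLN.

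Of the single genes, none passed in T cells cultured with PLN dendritic cells. The genes of smallest p on the higher side were Eef1a2 at 0.89 (SE 0.16; adjusted p = 0.931), Lmna at 0.55 (its other probe sets at -0.03, -0.12 and 0.06 with the block), Crim1 at 0.60, Alpl at 0.49 and Mrpl48 at 0.37. On the lower side were Igfbp5 at -0.82 (0.931; a weaker probe set stood at 0.38 with the block), the cytokine gene Il1b at -0.63, the lipid antigen presenter gene Cd1d1 at -0.50, Ap1s2 at -0.46 and the mitotic kinase gene Wee1 at -0.33. In limma 0 of 7436 genes passed (90 at an unadjusted p under 0.05). In the blocked fit Il17a, which encodes a cytokine, rose by 0.86 (adjusted p = 0.0241) and was the 1 gene called; it was not called with a random block by number. After median centring 4 rose and 1 fell with the block. The blocked count was 0 without Liver replicate 2, Liver replicate 4, MLN replicate 4 or any 1 PLN array, 2 without Liver replicate 3, and 3 without Spleen replicate 3 or Spleen replicate 4.

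As groups, type 2, regulatory, glycolysis and unfolded protein response genes were higher in PLN cultures and cell cycle and macrophage genes were lower. The mean that PLN is set against holds liver. In liver the type 2, regulatory, glycolysis, unfolded protein and cell cycle lists had medians of -0.61, -0.24, -0.17, -0.12 and 0.17. Part of these PLN shifts therefore comes from the liver arrays, and they are not separate from the liver ones. That mean holds spleen too, where the macrophage list had a median of 0.29, so its lower value in PLN is not separate from that shift. Of 11 type 2 genes 8 were higher, with a median of 0.34 (camera adjusted p = 0.00721; adjusted p = 0.711 with an estimated correlation), with Il24 at 1.34, Il10 at 0.69, Nfil3 at 0.48 and Ccr4 at 0.37. The regulatory T cell list, with Itgae at 0.25, Capg at 0.19 and Nrp1 at -0.31, had 11 of 15 genes higher and a median of 0.17 (0.0323; adjusted p = 0.194 with an estimated correlation). Of 17 glycolysis and hypoxia genes 12 were higher, with a median of 0.10 (0.0250; adjusted p = 0.711 with an estimated correlation), with Hk2 at 0.22 and Slc2a1 at 0.28. The unfolded protein and amino acid response list, with Trib3 at 0.65, Ddit3 at 0.57 and Herpud1 at 0.35, had 13 of 15 higher and a median of 0.10 (0.00211; adjusted p = 0.179 with an estimated correlation). Trib3 and Ddit3 were highest in PLN replicate 2 (11.19 and 10.06) and MLN replicate 2 (11.02 and 9.74), against 9.31 and 8.30 in PLN replicate 3. The same 2 arrays stood apart in the heat shock gene Hspa1a, at 10.23 and 9.91 against at most 7.11 on the others. The cause was not tested. The unfolded protein list stayed called when either array alone was left out. The other of the 2 then remained, so this does not show whether the call depends on them together. Of 30 cell cycle genes 25 were lower, with a median of -0.10 (0.000593; adjusted p = 0.711 with an estimated correlation), with Birc5 at -0.25, Ube2c at -0.24 and Ccna2 at -0.18. Of 6 macrophage markers 5 were lower, with a median of -0.33 (0.00211; adjusted p = 0.179 with an estimated correlation), with Cd14 at -0.53, Lyz2 at -0.51 and Fcgr3 at -0.40. The interferon-gamma response list, with Irgm1 at -0.26 and Irf1 at -0.17, had 10 of 12 lower and a median of -0.10 (0.0323; adjusted p = 0.328 with an estimated correlation), and was not called as deposited (median -0.08; 0.0609) or after median centring (-0.06; 0.0804). All 3 endothelial and stromal markers were higher, with a median of 0.28 (0.0103; adjusted p = 0.179 with an estimated correlation): Col1a2 at 0.48, Kdr at 0.28 and Pecam1 at 0.05.

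In these 8 PLN lists limma passed 0 genes over all genes tested in either fit, and without the block 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 2 cell cycle genes, 1 each of the glycolysis, interferon-gamma, unfolded protein and endothelial lists, and 0 of the type 2, regulatory and macrophage lists. In the blocked fit 6 type 2 genes, 3 regulatory and 3 glycolysis genes rose when adjusted over the list alone. The blocked fit called 6 of 29 lists; the interferon-gamma (0.0952) and endothelial (0.0611) lists were lost. The count of 8 was 2 without PLN replicate 4, 3 without PLN replicate 2, 4 without Spleen replicate 4 and 5 without MLN replicate 3. The cell cycle list was not called without PLN replicate 4 (0.511), the macrophage list without PLN replicate 2 (0.150), the type 2 list without MLN replicate 2, PLN replicate 3 (0.442) or Spleen replicate 4, and the unfolded protein list without PLN replicate 4 (0.0802) or Spleen replicate 4. The regulatory list stayed called only without Liver replicate 3 or Spleen replicate 3 (0.280 without PLN replicate 3). The glycolysis list was lost without Liver replicates 2 or 3, MLN replicate 3, PLN replicates 2 or 4 (0.507 for the latter) or Spleen replicate 3, and the interferon-gamma list without Liver replicate 3, MLN replicate 3, PLN replicates 2 (0.264) or 4, or Spleen replicates 3 or 4. With the block, the regulatory (0.103), glycolysis (0.0797) and macrophage (0.183) lists were lost without PLN replicate 2 and the unfolded protein list without PLN replicate 4 (0.0827), and the blocked count of 6 was 3 without PLN replicate 2.

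T cells cultured with spleen dendritic cells (n = 2) had higher macrophage markers as a group. Spleen had no array numbered 2, so unblocked comparisons with spleen also hold differences between the replicate numbers. All 6 macrophage, monocyte and Kupffer cell markers were higher, with a median of 0.29 (camera adjusted p = 0.00820; adjusted p = 0.216 with an estimated correlation). Cd14, a lipopolysaccharide receptor, stood at 0.95, Lyz2 at 0.37, Ctss at 0.34 and Csf1r at 0.24. Limma passed 0 of them in either fit (1 at an unadjusted p under 0.05, and 2 with the block); adjusted over the list alone it passed 0, and in the blocked fit Cd14 and Ctss rose. The rise was not particular to spleen. The mean of the other organs holds MLN and PLN, where this list had medians of -0.27 and -0.33, so these shifts are not separate. Relative to the mean of all arrays, the median of the list was 0.27 and 0.20 on the spleen arrays and 0.18, 0.17 and 0.15 on the liver arrays. On the MLN and PLN arrays it was at most 0.08. Single genes with the smallest p were Il1b at 1.12, Clec4n at 0.94, Mpp2 at 0.88, Cd1d1 at 0.59 and Hacd1 at 0.50 on the higher side, and Wipi2 at -0.81, Eml5 at -0.60, Mpst at -0.58, Incenp at -0.52 and Smc5 at -0.35 on the lower (adjusted p = 0.999 each). With the block other probe sets stood at 0.36 and 0.15 for Incenp, 0.10 for Smc5 and -0.01 for Wipi2, so these values rest on 1 probe set each. In limma 0 of 7436 genes passed (143 at an unadjusted p under 0.05), and 0 in the blocked fit (647); the unblocked count was 1 without Spleen replicate 3, and the blocked count 5 without Spleen replicate 3 and 8 without Spleen replicate 4.

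In the blocked fit camera called 4 lists in spleen cultures rather than 1. Besides the macrophage list (0.00724), the type 2 list had a blocked median of -0.24 (0.00724; 0.778 unblocked) and the NK cell list one of -0.21 (0.0118; 0.996 unblocked), with blocked adjusted p = 0.596 with an estimated correlation for all 3. The unblocked test of the NK cell list pointed down against a median of 0.10 and a mean of 0.04. For the cytotoxic list the direction turned: its unblocked test pointed up, with a median of -0.01 and a mean of 0.02 (0.996), and its blocked test pointed down, with a median of -0.06 (0.0353; adjusted p = 0.650 with an estimated correlation), or -0.16 as deposited and -0.26 after median centring. Members with the smallest p were Csf2 at a blocked -0.61 in the type 2 list, Cd244a at -0.48 in the NK cell list and Klrc1 at 0.43 in the cytotoxic list. Limma passed 0 members of these lists in either fit (0 at an unadjusted p under 0.05, and 2, 1 and 6 with the block); adjusted over the list alone 1 type 2 gene, 1 NK cell gene and 4 cytotoxic genes fell in the blocked fit, and 1 cytotoxic gene rose. The macrophage list was not called without Spleen replicate 3 (0.184), nor in the blocked fit without Spleen replicate 3 (0.0823) or 4. The blocked NK cell list was lost without Spleen replicate 3 (0.130) or 4, the type 2 list without Spleen replicate 4 (0.580), and the cytotoxic list without Liver replicate 2, Liver replicate 4, MLN replicate 3, PLN replicate 3 or Spleen replicate 3 (0.993). Unblocked, the count of lists was 2 without Liver replicate 3 or MLN replicate 4 and 5 without either spleen array; blocked, it was 7 without Liver replicate 3 and 1 without Spleen replicate 4. For every called list of the 4 organs the test, the median and the mean had the same sign. Among lists not called without the block they differed for the naive list in liver, PLN and spleen, cholesterol synthesis in liver, type 17 and CD8 T cell in MLN, gut homing, respiration, immediate early and CD4 T cell in PLN, and type 1, cytotoxic, activation, type I interferon, CD8 T cell and NK cell in spleen. A left-out spleen array leaves 1 spleen sample, which is then assumed to vary like the arrays of the other organs.

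Between pairs of organs, liver and MLN cultures differed most. Lmna was 2.45 (SE 0.22) higher in liver than in MLN on the log2 scale, with its weaker probe sets at 0.74, -0.16 and -0.82. Fut7 was higher in liver by 1.83 (SE 0.18) and Sema4a by 1.71 (SE 0.23). Gcnt2 was lower in liver, at -1.83 (SE 0.25), as were Hic1 at -1.48 (SE 0.15) and P2rx4 at -1.01 (SE 0.13). In limma 12 genes passed, 7 higher in liver and 5 lower, with adjusted p = 0.00243 for Lmna, 0.00255 for Fut7, 0.00325 for Hic1, 0.0226 for P2rx4 and 0.0227 for Sema4a and Gcnt2. Pdcd1 also passed, at 1.36 (0.0305), as did Csgalnact1, at -1.50 (0.0308). The blocked fit called 307 genes (184 with a random block by number), 140 higher and 167 lower in liver, and after median centring 80 higher and 152 lower. Lmna, Fut7 and Hic1 stayed past the threshold whichever array was left out. The count of 12 was 3 without Liver replicate 2 or 4, 4 without Liver replicate 3 or MLN replicate 3, 5 without MLN replicate 2, and 7 without PLN replicates 2 or 3 or either spleen array. Sema4a and P2rx4 were lost without any 1 liver array, MLN replicate 2 or MLN replicate 3 (highest adjusted p = 0.0996 and 0.0930), and Gcnt2 without any 1 liver or MLN array (0.125). The blocked count was 71 without MLN replicate 2, 89 without Liver replicate 2, 104 without MLN replicate 4, 138 without Liver replicate 4 and 163 without MLN replicate 3.

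Lmna was also lower in MLN than in PLN cultures, at -1.98 (SE 0.22) with 1 of 3 other probe sets of opposite sign, and was the 1 gene that passed in limma (adjusted p = 0.0192). It did not pass without Liver replicate 2, MLN replicate 3, MLN replicate 4 or any 1 PLN array (0.165 without PLN replicate 3), and it passed the blocked fit in every such case. In the blocked fit 11 genes differed between MLN and PLN, 2 higher and 9 lower in MLN; 7 did without PLN replicate 2 or 4 and 6 without PLN replicate 3. Between MLN and spleen limma passed 0 genes (261 at an unadjusted p under 0.05), 1 without Liver replicate 4 or MLN replicate 2, and the blocked fit 16, with 3 higher and 13 lower in MLN, 34 without Spleen replicate 3 and 10 without MLN replicate 4. Lmna was among the 16, at -1.91 (0.000213). After median centring that split was 31 higher and 20 lower. Between liver and PLN limma passed 0 genes (275 at an unadjusted p under 0.05) and the blocked fit 112, with 31 higher and 81 lower in liver. Only 4 passed with the number as a random block. Fut7, at 0.77 (0.0435), and Il10, at -1.05 (0.0449), were among the 112. That count was 2 without Liver replicate 2 or PLN replicate 2, 6 without Liver replicate 4, 1 without PLN replicate 4, 68 without MLN replicate 2, 71 without MLN replicate 4 and 230 without Liver replicate 3. Limma passed 0 genes in either fit between liver and spleen (131 at an unadjusted p under 0.05, and 644 with the block) and between PLN and spleen (116 and 605). With the block these counts were 2 without Liver replicate 3, 1 and 6 without Spleen replicates 3 and 4 for liver and spleen, and 3 and 5 without Spleen replicates 3 and 4 for PLN and spleen.

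Of the genes fixed in advance for homing, cytokines and lineage, Fut7 alone passed between liver and MLN cultures. The gut homing receptor gene Ccr9 stood at -1.29, liver minus MLN, with group means of 5.78 ± 0.58 and 7.07 ± 1.68 (SD, n = 3), and its level was below that of the tested genes. Itga4, which encodes an integrin chain of gut-homing cells, stood at -1.01 (limma adjusted p = 0.571; blocked 0.0864), and its partner Itgb7 at -0.26. The lymph node homing receptor gene Ccr7 (-0.09), the selectin ligand gene Selplg (0.12) and Cd44 (0.36) did not pass, nor did Il2ra (-0.23), Ifng (-0.55), Il10 (-0.32), Tbx21 (0.33), Gata3 (-0.30), Gzmb (-0.06) and Mki67 (0.24). Il4 stood at -1.36 and Foxp3 at 0.16, both below the level of the tested genes.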

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

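Planned before the data were seen were the settings of the unblocked fit; those within the blocked fit were chosen afterwards. None of the 47 named gene differences changed sign under a setting that keeps 1 value per gene. Of 28 whose gene has further probe sets, 10 had at least 1 probe set of opposite sign in the blocked fit: Lmna in each of its comparisons, Eml5 and Gcnt2 in liver, Igfbp5 in PLN, and Incenp and Smc5 in spleen. For the named genes, 879 unblocked alternatives kept direction and call, 45 lost a call and 29 gained one; with the block these were 830, 57 and 2. For the named lists 436 alternatives kept both, 117 lost the call and 9 gained one, and with the block 438, 60 and 18. The sign of the test turned in 2 and 1 cases, all of them the cytotoxic list in spleen. The median of the NK cell list in spleen also turned, from 0.10 to -0.21 with the block, while its test kept its sign. Spleen has no array numbered 2, so its unblocked values also carry the difference between number 2 and the other numbers. Relative to the mean of all arrays, the NK cell list stood at -0.83, -0.57 and -0.48 on the arrays numbered 2. On those numbered 4 it stood at 0.49 to 0.93. The turn of its median with the block goes with this imbalance. The cause of the other changed results was not tested. Genes of low level are limited by background, as 12.9% to 16.5% of probe sets per array lay below an intensity of 16.

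With the replicate block the counts of genes were 148 among the organs, 159 for liver, 99 for MLN, 1 for PLN, 307 between liver and MLN, 112 between liver and PLN, 11 between MLN and PLN and 16 between MLN and spleen, and lists numbered 3 for MLN and 4 for spleen. Beyond these it changed no other count by more than 1.5 times. Beyond the calls given with the results, it changed no other call of the lists or of the 47 named gene differences. With the number as a random block the counts of genes were 51 among the organs, 47 for liver, 59 for MLN, 184 between liver and MLN, 4 between liver and PLN, 10 between MLN and PLN and 13 between MLN and spleen, with none for PLN; camera takes no random block, so lists were not run. The cytotoxic list in spleen, with a median of -0.00705 and no call, reversed the sign of its test to a median of -0.0575 with the replicate block, to -0.368 without Spleen replicate 4; without Spleen replicate 3 it was 0.641. Within the blocked fit it reversed to -0.0448 without Spleen replicate 3, was -0.152 without Spleen replicate 4 and lost its call at -0.0335 without Liver replicate 4.

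Without the block, lists in spleen numbered 4 as deposited and 4 after median centring, which gave 8 in MLN. With no level filter 1 gene was called for liver and 6 between liver and MLN, with 2 lists in MLN, 5 in PLN and 0 in spleen. With the upper 40% of genes, 4 genes were called for MLN and 5 between liver and MLN, with 3 lists in MLN and 0 in spleen. The mean of probe sets gave 7 genes between liver and MLN, 0 between MLN and PLN, and 5 lists in PLN. Ranks gave 1 list in MLN, only the 2 organs gave 4 genes between liver and MLN, and an estimated correlation gave 0 lists in each organ, also with the block.

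With the block, lists numbered 9 in MLN and 9 in spleen as deposited. Median centring gave 5 genes for PLN, 51 between MLN and spleen, and 9 lists in MLN, 10 in PLN and 7 in spleen. With no level filter the genes were 45 among the organs, 43 for liver, 59 for MLN, 0 for PLN, 168 between liver and MLN, 5 between liver and PLN and 9 between MLN and spleen.

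Leaving out 1 array in the unblocked fit gave 0 to 3 genes among the organs, 0 to 2 for liver, 2 to 9 for MLN, 0 for PLN, 0 to 1 for spleen, 3 to 9 between liver and MLN, 0 to 1 between MLN and PLN and between MLN and spleen, and 0 for the other pairs. Lists then ranged from 3 to 11 in liver, 2 to 6 in MLN, 2 to 10 in PLN and 1 to 5 in spleen. In the blocked fit, leaving out 1 array or all arrays of 1 number gave 15 to 185 genes among the organs, 5 to 208 for liver, 22 to 131 for MLN, 0 to 14 for PLN and 0 to 8 for spleen. Between pairs these were 60 to 321 for liver and MLN, 0 to 243 for liver and PLN, 0 to 6 for liver and spleen, 5 to 12 for MLN and PLN, 7 to 40 for MLN and spleen, and 0 to 10 for PLN and spleen. Blocked lists ranged from 6 to 11 in liver, 3 to 10 in MLN, 3 to 8 in PLN and 1 to 7 in spleen. Without all arrays numbered 2, 5 genes were called for liver and 27 for MLN, and without those numbered 4, 22 and 22.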

Other observations

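The tests in this part were chosen after the results were seen, except those of retinoic acid targets and of further myeloid genes, whose predictions were written before those genes were looked at.

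The replicate numbers, which the labels leave undescribed, went with a strong difference in T cell effector genes and in cell type markers. With the organ as a block, arrays numbered 4 exceeded those numbered 3 in the granzyme genes Gzmg by 3.35, Gzmf by 2.45, Gzme by 2.10 and Gzmd by 1.83, and in the perforin gene Prf1 by 1.63 (limma adjusted p at most 5.23e-06). Of 19 cytotoxic genes 13 rose (camera adjusted p = 3.83e-05; adjusted p = 0.406 with an estimated correlation), and the 4 NK cell markers all rose, Klra7 by 1.16 and Fcer1g by 1.15. In the same arrays 16 of 30 cell cycle genes fell (0.000520; adjusted p = 0.406 with an estimated correlation), and 10 of 12 dendritic cell markers fell (0.00221; adjusted p = 0.406 with an estimated correlation), with Ccl22 at -1.83. From number 2 to number 3, 7 of 11 type 2 genes, 5 of 12 dendritic cell markers and 2 of 4 NK cell markers rose (2.69e-05, 0.000410 and 0.0130; adjusted p = 0.263 each with an estimated correlation). Of cytokine genes chosen after their values were seen, Il13 rose by 2.84, Csf2 by 1.66 and Il3 by 1.59 in that step, and in number 4 they were below number 3, at -1.41, -1.62 and -1.67. Ifng rose by 1.68 from number 2 to number 3 and differed by 0.02 between numbers 4 and 3 (limma adjusted p = 0.928). Between numbers 4 and 3, 3 of 5 CD8 T cell and 3 of 5 B cell markers also rose (medians 0.44 and 0.51), and 2 of 3 CD4 T cell markers fell (median -0.34). Camera called none of these lists (adjusted p = 0.113, 0.222 and 0.222). Whether the effector genes differ through the mix of cells was not tested. In all, 3219 genes differed between numbers 4 and 3, 2025 between 4 and 2, and 1404 between 3 and 2.

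Genes chosen after their values were seen in the blocked fit add detail to the contrast of liver and MLN cultures. The transglutaminase gene Tgm2 showed the largest difference on the lower side in liver, by -2.13 against the other organs (limma adjusted p = 0.00108), and rose by 1.66 in MLN (0.00320). Tgfb3 fell by 1.71 in liver (0.0139) and Il13 was lower in liver than in MLN, at -1.54 (0.0140). The chemokine genes Ccl4 and Ccl5 rose by 0.63 and 0.62 in liver cultures (0.0238 and 0.0467), and S100a4, a marker of effector and memory cells, rose by 0.87 (0.00392). In MLN cultures Il18r1 and Klrc1 fell by 1.47 and 1.25 (0.00251 and 0.000427), and Lztfl1, 1 of several neighbours of Ccr9 in the reference annotation, rose by 1.17 (0.000703). A shared effect on the Ccr9 region was not tested. Immunoglobulin genes Igha and Ighg3 also rose in MLN, by 1.07 and 0.89 (0.0405 and 0.0331). Without the replicate block none of these genes passed in these comparisons. With it, the B cell and plasma cell lists were not called in MLN (medians 0.05 and 0.07, camera adjusted p = 0.451 and 0.577). The source of the immunoglobulin transcripts was not tested.

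Other splits of the arrays were used to ask whether the counts could arise by chance. Splits over all arrays without the block ignore the replicate number. Among 100 of them, 9 gave as many genes among the organs (real 3, highest other 968), 4 for MLN (7 and 671), and for lists 17 in liver (7 and 8), 47 in MLN (5 and 12) and 6 in PLN (8 and 8). The real counts of 0 for liver and PLN are reached by any split, so the 100 of 100 for each (highest other 1482 and 830) decide nothing. The splits with 1482, 830 and 671 genes put 3 arrays of 1 replicate number together as an organ, which points to a structure of the samples by number, so the share for MLN is not a measure of chance for the organ. Splits within numbers part as many arrays of a number as the real one. For the unblocked counts, 2 of 100 reached the 3 genes among the organs (highest other 3) and 2 the 7 of MLN (7). The split that did so besides the real one kept the 3 MLN arrays together. These shares make chance unlikely there but do not exclude it, as an organ's 3 arrays can be picked within numbers in only 48 ways. For unblocked lists, 12 reached the 7 of liver (9) and 28 the 5 of MLN (9), where chance could not be excluded, and 4 the 8 of PLN (9), a share under 0.05 that did not hold with the block. List by list, the exact permutation within numbers gave the called lists p = 0.0208 to 0.0625 in liver (adjusted p at least 0.0755), 0.0208 to 0.208 in MLN (0.302), 0.0208 to 0.292 in PLN (0.604) and 0.125 in spleen (0.725), so no single list passed when adjusted over the 29. The design nearly fixed this outcome. The smallest possible p is 0.0625 with the 16 ways of spleen and 0.0208 with the 48 ways of the other organs. An adjusted p under 0.05 would need many lists tied at 0.0208, so the adjusted values do not judge single lists. With the block and splits within numbers, 1 of 100, the real one, reached the count among the organs (148; highest other 53), for liver (159; 116) and for MLN (99; 47), so chance is unlikely there, though not excluded. Chance stayed open for PLN genes, with 12 of 100 (1; 63), where the highest gave the PLN label to the 3 MLN arrays, and for lists, with 9 in liver (8; 9), 59 in MLN (3; 9) and 28 in PLN (6; 8). Pairs of 3 arrays allow only 10 splits, too few for a share under 0.05: 1 reached the 12 genes of liver and MLN (highest other 1) and 2 the 1 of MLN and PLN (1), while the real 0 of liver and PLN is reached by all 10 (highest other 0).

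The genes that differed between MLN and liver cultures could reflect, among other causes, carried-over dendritic cells, a different balance of CD4 and CD8 T cells, or a retinoic acid response. The 12 dendritic cell markers were 0.28 (bootstrap SE 0.14) higher in MLN at the median, barely within 2 SE of 0. The bootstrap resampled the 12 genes and not the arrays, so this SE does not measure the spread between cultures. Carry-over stays open. Cd8a and Cd8b1 had a mean log2 difference, liver minus MLN, of 0.0151, and the mean of their single SEs was 0.09. That mean joins opposite differences, as Cd8a was lower and Cd8b1 higher in liver at the group means. Klrk1, Klrc1 and Klrd1 were 1.18 higher in liver at the median, which argues against that balance as the whole cause for these 3 genes. The median of 10 retinoic acid targets, at 0.14 with 7 higher in MLN, lay at percentile 92.0 of 10000 random lists of matched level, below the 95 set beforehand, so that hypothesis stays open. Its members were uneven: Crabp2, Stra6, Dhrs3 and Cyp26a1 were 2.10, 1.90, 1.50 and 1.15 higher in MLN, each in 3 of 3 numbers, with Stra6 alone passing over 12393 genes (blocked limma adjusted p = 0.0263; unblocked 0.171) and 3 passing adjusted over the list alone, at low levels, while Rara, Nrip1 and Rarg stood at 0.12, 0.06 and -0.36.

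The higher cell cycle list in liver cultures may reflect scaling between arrays, chance, or more cycling cells. With the block, its median was at least 0.18 and its camera adjusted p at most 5.02e-07 under both other scalings, which argues against the quantile normalization as its source. These scalings differ from each other only by a constant per array. A test against the other genes hardly registers such a constant, so they count as a single check. The liver array had the highest list mean in 3 of 3 numbers, an exact permutation p = 0.0208 within numbers, the smallest that 48 ways can give and shared by 7 other lists in liver. Over the 29 lists the adjusted value is 0.0755, but it is set by how many lists tie at that p and cannot decide for this list. Chance stays open, as it does for the number of called lists. More cycling cells therefore remain a hypothesis, and no measure of division outside RNA was used here.

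The higher macrophage list in spleen cultures may come from myeloid cells carried over with the dendritic cells. Of 12 further myeloid genes, 7 were higher with a median of 0.11, at percentile 91.3 of random lists of matched level, between the 50 and 95 set beforehand, so carry-over stays open. Clec7a, at 0.78, and Spi1, at 0.43, had the largest values and did not pass (limma adjusted p = 0.404 and 0.635). With 2 spleen arrays, an effect of the spleen dendritic cells on T cells was not separated from carry-over. The fixed macrophage list was also high on the liver arrays, so its rise is not particular to spleen.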
